A study of Drosophila melanogaster with 3 samples.

How the data were processed

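Replication timing was measured in S2-DRSC cells, a male Drosophila melanogaster cell line derived from embryos, on 3 two-colour tiling arrays. Per the labels' protocols, cells were grown at 25 °C and split into 2 populations, both held with 1 mM hydroxyurea, which stalls DNA synthesis by lowering the supply of nucleotides. The early population received hydroxyurea for 3 h and then the thymidine analogue BrdU at 50 µg/ml for a further 21 h, followed by 1 h with BrdU after release. The late population was held in hydroxyurea for 24 h, released for 3 to 4 h and given BrdU for 2 h. DNA carrying BrdU was recovered with an antibody, labelled with Cy3 or Cy5 and hybridised to arrays of genomic probes.

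Each array had its own slide and scan, so no slide or scan held more than 1 array and neither could be tested as a batch. The labels give the dye of each channel. Channel 1 was Cy5 on replicates 1 and 3 and Cy3 on replicate 2. They do not state which channel held the early and which the late population, so no ratio is read here as early over late. The sample titles number 3 extractions and do not say whether these came from separate cultures. The limma p-values from the 3 arrays therefore measure only the spread between these samples, which may be technical. The p-values from circular shifts and from permutations of domain lengths, described below, do not measure that spread.

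The deposited scanner files hold 243273 spots per array, of which 241469 are genomic probes of 45 to 60 nt and 1804 are controls. Per the file headers, spot and background intensity values were extracted with Agilent Feature Extraction 9.5.1.1, which subtracted background, removed spatial trends and applied a linear dye factor to each channel to give processed signals. Per the file headers, the ratio column is the log10 of the red (Cy5) over the green (Cy3) processed signal. Recomputing it from the processed signals gave the same value within 0.001 for over 99.8% of probes on each array. A deposited table from the authors holds log2 ratios and mean log2 intensities of the same spots. Limma, named without a version, is the only tool in the submitters' processing notes, and the background correction and normalization behind that table are not given in the sources used here. Its log2 ratios correlated with the scanner ratios at r = 0.978, 0.968 and 0.959 on replicates 1, 2 and 3, so they are red over green. Their medians were -0.015, -0.0041 and 0.0051.

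The main values were the scanner files' log10 ratios converted to log2 and centred on each array's median over genomic probes. No loess or quantile step was applied, because most probes carry signal in both channels. Control spots were dropped and spots with an outlier flag were treated as missing, which removed 41, 332 and 18 probes on replicates 1, 2 and 3. Probe coordinates are those of Drosophila genome Release 5.1 as given in the files, with a median spacing of 470 bp. Probe ratios were averaged in 10 kb windows with at least 5 probes, giving 12092 windows with a median of 21 probes. Window and probe means over the arrays were tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with tables read by the data.table package (version 1.17.8) and Benjamini-Hochberg adjustment at 0.05.

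The design fixed before the data were examined turned every ratio to channel 1 over channel 2 by the labelled dyes. Because replicate 1 then ran opposite to the other 2 arrays, a second set of signs was added after seeing the data and is called aligned. It takes red over green on replicates 1 and 2 and green over red on replicate 3. The DNA in the numerator of the aligned ratio is called the A side and the DNA in the denominator the B side. The names carry no early or late meaning, and turning all 3 signs exchanges A and B without changing any size or p-value.

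Domains were runs of adjacent windows called the same way, joined across at most 1 uncalled window and holding at least 3 called windows. Differences between chromosomes were tested on the mean window profile with 10000 seeded circular shifts along the concatenated arms, two-sided, which keeps the order of neighbouring windows. For chromosome 4 against the other autosomes, all 9546 possible shifts were used. An exact sign-flip permutation over 3 arrays cannot give a two-sided p below 0.25. The arm-proximal region was the 2 Mb next to the centromere on each of the 5 long arms. Domain lengths were compared with 100000 permutations. These tests of length, and those of each arm against the rest, were added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used for these steps.

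The only annotation table given is on another genome release than the probes, so no probe was placed in a gene. The planned tests of genes, of gene lists and of gene density were not run, and GC content was taken from the probe sequences in place of the genome. By the rule fixed in advance for this case, only regions are named. These are, for each side, the 4 longest domains and the 4 domains with the largest absolute mean ratio.

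The limma step was tested on 12092 simulated windows with the spread of the aligned fit, of which 200 had known ratios on the log2 scale. It recovered 100% of the 50 windows changed by 0.5 and of the 50 changed by 1. At 0.25 it recovered 46%, and at 0.15 it recovered 8%. False calls made up 1.55% of all calls. These shares do not carry over to the real calls. The simulation changed only 200 windows, with independent noise and fixed signs, while 10027 windows were called with the aligned signs. The smallest size called there was 0.136. The circular-shift test of the X against the autosomes was tested on 500 simulated profiles of 11714 windows with the real correlation between neighbours. It passed 0.05 in 4.8% of profiles with no difference and in 98.8% of those with an added difference of 0.36. The domain step found 100% of 40 planted runs with their exact ends. These runs held no noise, and their only gaps were single uncalled windows, which the rule joins. The result checks the joining rule and says nothing about how exact the ends of real domains are.

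The alternatives were normexp background correction (offset 50) with and without loess, the authors' deposited table, no centring, a dye term in the fit and only probes well above background. Others were leaving out each array, array weights, windows of 5 or 50 kb, an adjusted p of 0.01, no joining of windows into domains, medians in place of means, and proximal regions of 1 or 4 Mb.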

Results

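Genomic DNA labelled with BrdU in the early and the late population of S2-DRSC cells was compared across the Drosophila genome. The question was which regions replicate at different times in S phase. The data are 1 group of 3 arrays, each carrying both labelled DNA populations in opposite dyes. At least 99.78% of probes were well above background in each channel of each array. The median background-subtracted signal of genomic probes was 479 in green and 496 in red on replicate 1, 446 and 686 on replicate 2, and 401 and 641 on replicate 3, in scanner units. Negative control spots averaged between 1.04 and 5.59 in the same units. Of the 241469 genomic probes, 745 were not well above background in at least 1 channel of at least 1 array. The number of arrays, 3, limits the precision of every value given here.

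The 3 arrays held the same profile along the chromosomes, but 1 of them was its mirror image. Across 10 kb windows, red over green correlated at r = 0.989 between replicates 1 and 2, at r = -0.976 between replicates 1 and 3 and at r = -0.965 between replicates 2 and 3. Single probes gave 0.959, -0.942 and -0.918 for the same pairs. These correlations are across windows and probes, which are not independent replicates. Channel 1 was Cy5 on replicates 1 and 3, so the labelled dyes put replicates 1 and 3 the same way round and replicate 2 the other way. With the ratios turned to channel 1 over channel 2, replicates 2 and 3 correlated at 0.965, while replicate 1 correlated at -0.989 and -0.976 with them. The direction of the ratios is therefore not settled by the labels.

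**Figure D1:**
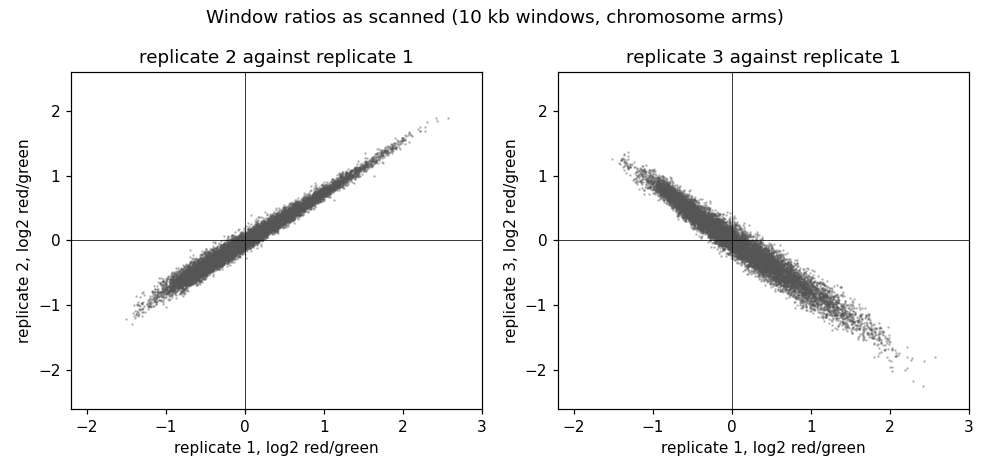
Log2 red over green of each 10 kb window on the chromosome arms, with replicate 1 on the x axis and replicate 2 (left) or replicate 3 (right) on the y axis, as scanned and centred on each array's median. Points rise along a line for replicate 2 (r = 0.989) and fall along one for replicate 3 (r = -0.976).

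Under the labelled dyes, no window or probe passed the test for a difference between the channels. Limma called 0 of 12092 windows and 0 of 241469 probes at an adjusted p of 0.05, and the smallest adjusted p of a window was 1.00. At an unadjusted p under 0.05 it gave 0 windows and 13 probes, and no other test was run on windows or probes. The sign of the ratio was the same on all 3 arrays in 1.4% of windows. Without replicate 1, 9548 windows were called, of which 4985 were higher in channel 1 and 4563 lower. With array weights, 11280 were called, since the weights were 0.029 for replicate 1, 48.9 for replicate 2 and 0.71 for replicate 3, so that replicate 2 set the result.

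With the signs aligned, most windows were called on the A or the B side, in alternating domains. Of 12092 windows, 4826 (39.9%) were called on the A side, 5201 (43.0%) on the B side and 2065 on neither. Called windows had a median size of 0.48 on the log2 scale, and the smallest was 0.136. The sign was the same on all 3 arrays in 91.2% of windows. The median SD between arrays was 0.094 on the log2 scale, against an SD of 0.56 between window means. A-side ratios reached further than B-side ratios. The window means ran from 2.19, a 4.55-fold excess of the A side, to -1.37, a 2.58-fold excess of the B side, and 683 windows lay above 1 against 105 below -1. At the level of single probes, 90269 were called on the A side and 90251 on the B side. The split follows from centring each array on its probe median, and without centring it was 82045 and 97935 probes, and 4453 and 5641 windows.

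These calls rest on signs chosen after the data were seen, and with all 3 signs turned the A and B counts change places. Limma estimated that all windows share 1 spread, with a standard error of 0.067 per window, although the SD between arrays reached 0.42 in the window with the third highest mean.

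Called windows formed 875 domains that covered 96.9 Mb. The 414 A domains covered 46.19 Mb and the 461 B domains 50.71 Mb, and the median length was 70 kb on both sides. Mean lengths were 112 kb for A and 110 kb for B domains (permutation p = 0.824, domains taken as independent). Neighbouring windows were alike over short distances. Between windows 10 kb apart the ratios correlated at 0.905 (2R) to 0.936 (3L) on the long arms, at 50 kb at 0.414 (2R) to 0.577 (3L), and at 200 kb at -0.013 (2R) to 0.098 (2L).

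**Figure D2:**
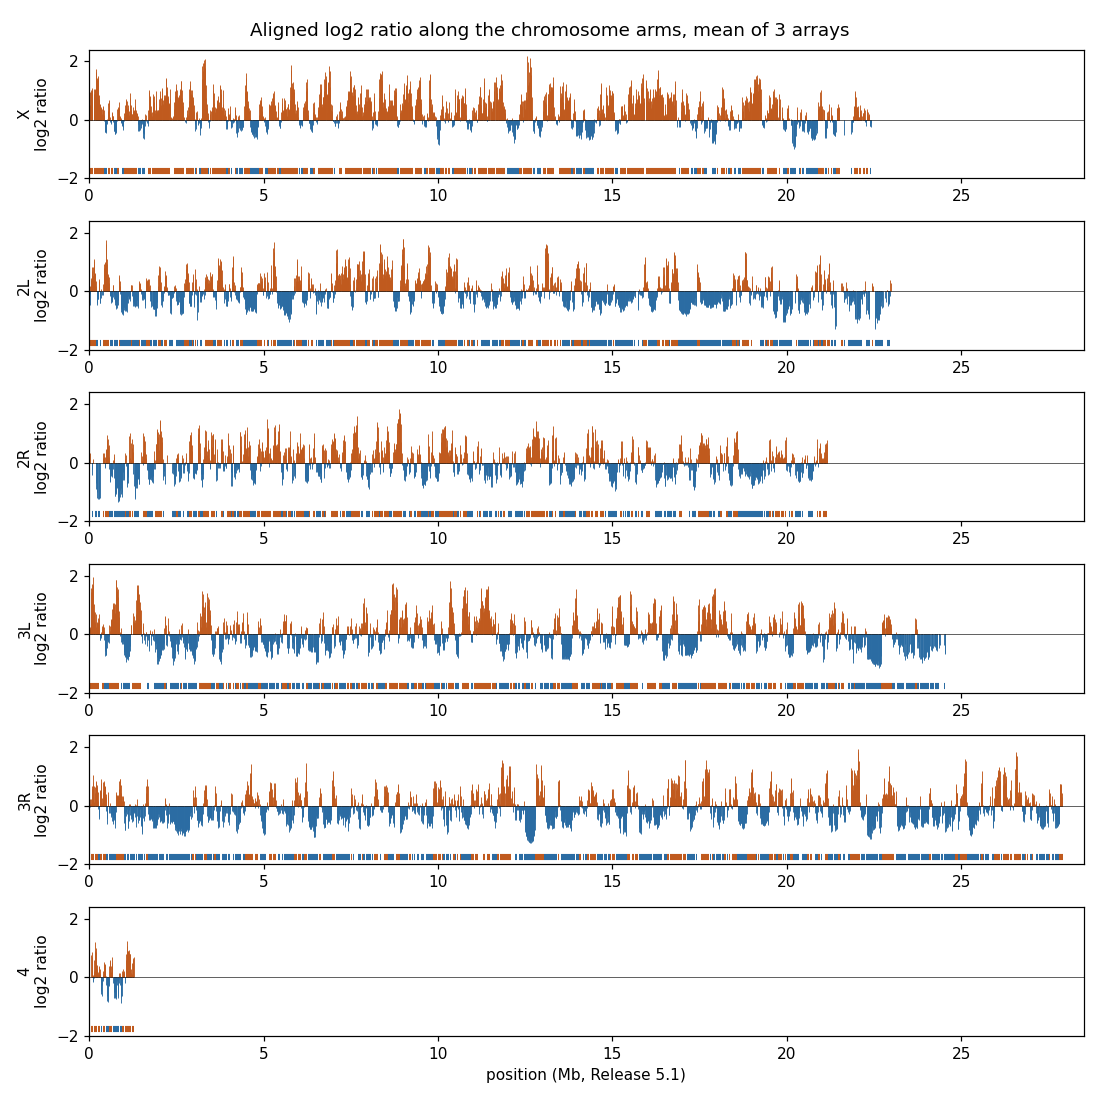
Aligned log2 ratio (y axis, mean of 3 arrays) of each 10 kb window along the X, 2L, 2R, 3L, 3R and 4 (x axis, position in Mb, Release 5.1), orange above 0 (A side) and blue below (B side). The strip at the bottom of each panel marks the domains in the same colours, and windows called on the A side make up 61.1% of the X against 30.9% of 3R.

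The longest A domains all lay on the X chromosome. The longest spanned X 15950001-16830000, 880 kb with 1809 probes, at a mean log2 ratio of 0.78 ± 0.12 (SD, n = 3 arrays here and below). It was followed by X 18700001-19270000 (570 kb) at 0.83 ± 0.13, X 8280001-8820000 (540 kb) at 0.77 ± 0.11 and X 1810001-2330000 (520 kb) at 0.67 ± 0.13. The longest B domains lay on the autosomes. They were 2R 18600001-19310000 (710 kb) at -0.46 ± 0.07, 3R 2290001-2900000 (610 kb) at -0.74 ± 0.07, 2L 17510001-18110000 (600 kb) at -0.43 ± 0.08 and 3L 16870001-17430000 (560 kb) at -0.55 ± 0.05.

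By size of the ratio, the highest A domain was 2L 13050001-13170000, 120 kb with 256 probes, at 1.29 ± 0.19, a 2.45-fold excess of the A side. X 3220001-3410000 stood at 1.22 ± 0.21 over 190 kb and 3L 8600001-8840000 at 1.07 ± 0.13 over 240 kb. U 5280001-5310000, on the sequence of unplaced scaffolds, stood at 1.1 ± 0.25 over 3 windows with 34 probes, but at 0.51 in the authors' deposited table and at 0.51 after normexp and loess. The strongest B domain was 2R 260001-320000, close to the centromere, at -1.22 ± 0.20 with 39 probes. In the proximal part of 3L, 22280001-22710000 stood at -0.91 ± 0.15 over 430 kb. The others were 3LHet 870001-950000, on a heterochromatin scaffold, at -1.07 ± 0.18 with 67 probes, and 3R 12470001-12790000 at -1.04 ± 0.11 over 320 kb. Each of these 16 domains had the same sign on all 3 arrays. The signs were aligned and the domains picked on these same arrays, so this is no separate support. Under the labelled dyes the same regions had means from -0.28 to 0.31, with replicate 1 opposite to the other 2.

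**Figure D3:**
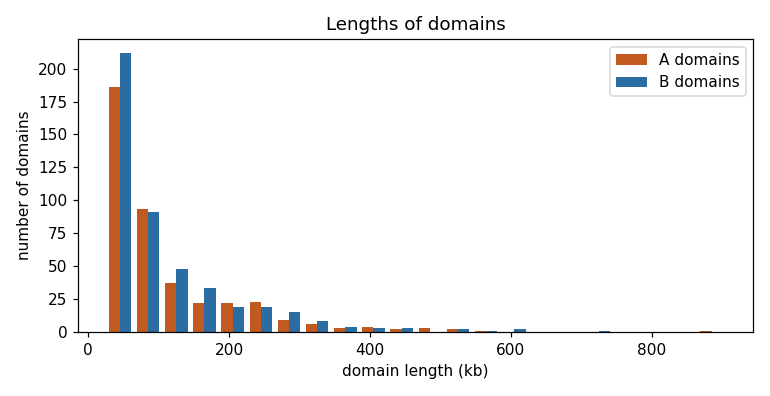
Number of domains (y axis) by length in kb (x axis, bins of equal width), for the 414 A domains (orange) and the 461 B domains (blue). Both sides have a median of 70 kb, with tails to 880 kb (A) and 710 kb (B).

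The X chromosome lay further to the A side than the autosomes. Its windows averaged 0.33 against -0.03 on the autosomes, a difference of 0.36 ± 0.05 with 0.42, 0.34 and 0.32 on replicates 1, 2 and 3. On the X, 61.1% of windows were called on the A side and 21.3% on the B side, against 34.5% and 49.4% on 2L, 39.7% and 40.3% on 2R, 36.9% and 45.9% on 3L, and 30.9% and 52.3% on 3R. The circular-shift permutation p was 0.0143, or 0.0429 after Benjamini-Hochberg adjustment over the 3 planned comparisons of chromosomes. Without replicate 2 the difference was 0.37 and the adjusted permutation p 0.0546, so the call was lost. As 1 of 6 arms each set against the rest, the X had an adjusted permutation p of 0.0858, and the other 5 arms had 0.765 or more.

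With all signs turned the X difference is -0.36. Under the labelled dyes it was -0.08 ± 0.43, with 0.42 on replicate 1 against -0.34 and -0.32 on replicates 2 and 3. The circular-shift permutation p of that mean profile was 0.008 (adjusted 0.024), but the difference was smaller than the spread between arrays and became 0.05 without replicate 2 (adjusted permutation p = 0.012) and 0.04 without replicate 3 (adjusted 0.0528).

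The small chromosome 4, largely heterochromatic along its length, alternated between the sides like the long arms. Of its 121 windows, 52.1% were called on the A side and 30.6% on the B side. Its mean exceeded that of the other autosomes by 0.16 ± 0.08 (0.21, 0.07 and 0.19 on replicates 1, 2 and 3), or -0.16 with all signs turned, with a circular-shift permutation p of 0.439 (adjusted 0.439). The labelled dyes gave -0.02 ± 0.21 (permutation p = 0.730), with 0.21 on replicate 1 against -0.07 and -0.19 on replicates 2 and 3. Without replicate 3 it gave 0.07 and passed the test (adjusted permutation p = 0.0214), but as a mean of 2 arrays of opposite sign.

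Next to the centromeres, 2L, 2R and 3L lay on the B side, by an amount that depended on the size of the region. Over the planned 2 Mb, the proximal windows averaged -0.30 on 2L, -0.22 on 2R and -0.36 on 3L, which was below the rest of the arm by -0.28 ± 0.02, -0.27 ± 0.01 and -0.38 ± 0.05. On the X they averaged near 0, at -0.0029, against 0.36 on the rest of the arm, a difference of -0.36 ± 0.04. On 2L the difference was -0.45 ± 0.03 over 1 Mb and -0.24 ± 0.03 over 4 Mb, and on 3L -0.53 ± 0.07 and -0.33 ± 0.05. On 2R it was -0.47 ± 0.04 over 1 Mb and -0.09 ± 0.02 over 4 Mb, and on the X -0.13 ± 0.03 and -0.22 ± 0.03. On 3R it changed sign with the size of the region and was 0.05 ± 0.02 over 2 Mb, 0.34 ± 0.06 over 1 Mb and -0.14 ± 0.02 over 4 Mb. The proximal 1 Mb of the X lay on the A side, with a mean of 0.20. Over 2 Mb and all 5 arms together the difference was -0.23 ± 0.02, or 0.23 with all signs turned, and did not pass the circular-shift test (permutation p = 0.0971, adjusted 0.146). The labelled dyes gave 0.06 ± 0.27 (permutation p = 0.0741, adjusted 0.111).

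The scaffolds of pericentric heterochromatin, the repeat-rich DNA around centromeres known to replicate late in Drosophila, lay on the B side for 2L, 2R, 3L and the X but not for 3R. Probe means were -0.75 ± 0.05 on 2LHet (78 probes), -0.64 ± 0.09 on XHet (161 probes), -0.53 ± 0.06 on 2RHet (1169 probes) and -0.49 ± 0.03 on 3LHet (1052 probes). All 7 windows of 2LHet and all 11 of XHet were called on the B side, as were 95.2% on 2RHet and 82.8% on 3LHet. By contrast, 3RHet was mixed, with 55.9% of its 68 windows on the A side, 38.2% on the B side and a mean of 0.04 ± 0.11. YHet stood at 0.16 ± 0.05 and the unplaced sequence U at 0.18 ± 0.07, but 35.4% of the 158 YHet probes and 12.5% of the 1243 U probes were not well above background. Without these probes the means were 0.20 on YHet and 0.19 on U. No test was made between scaffolds and arms, and the labels do not tie either side to the late population.

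**Figure D4:**
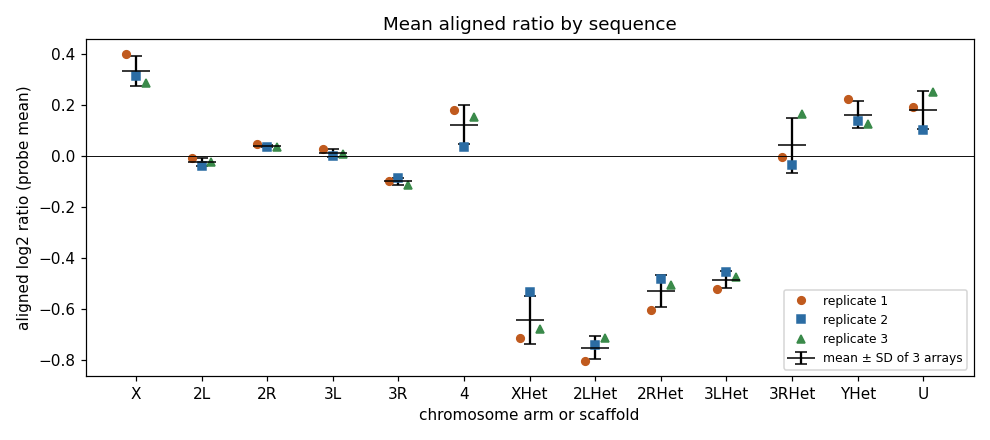
Mean aligned log2 ratio (y axis) of all probes on each chromosome arm and scaffold (x axis), with 1 point per array and the mean ± SD of the 3 arrays in black. The X stands at 0.33 and 4 of the scaffolds between -0.75 and -0.49, while 3RHet, YHet and U lie at or above 0.04.

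GC content followed the ratio only weakly. Across 11714 windows on the arms, the mean aligned ratio and the GC content of the probes gave Spearman's rho = 0.099 (circular-shift permutation p = 0.0001, the smallest that 10000 shifts can give) and Pearson's r = 0.071 (permutation p = 0.0004). After adjustment over the 4 profiles tested these were 0.000133 and 0.0008. Pearson's r on replicate 3 was 0.033 and did not pass the test (permutation p = 0.117), while Spearman's rho there was 0.059 and passed (permutation p = 0.0025). The labelled dyes gave rho = -0.118, and 0.136 without replicate 2. Windows are not independent replicates.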

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

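The aligned signs were chosen after seeing the data. They changed the count of called windows from 0 to 10027, with 4826 higher and 5201 lower, in 875 domains over 96.9 Mb, and the count of called probes from 0 to 180520. They turned the X minus autosome difference to 0.3603, that of chromosome 4 to 0.1574, that of the proximal regions to -0.2312, the rho with GC to 0.09854, and the correlations of replicate 1 with replicates 2 and 3 to 0.9887 and 0.9764. Since the overall sign of the aligned ratios is arbitrary, these turns show only that the labelled mean follows the arrays opposite to replicate 1. Under the labelled dyes, array weights gave 11280 windows, 5907 higher and 5373 lower, in 879 domains over 109.42 Mb, because they left the fit to replicate 2, and the fit of the weights did not converge. Leaving out each array in turn gave 0 to 9548 windows, 0 to 4985 higher, 0 to 4563 lower, 0 to 838 domains over 0 to 92.28 Mb and 0 to 159414 probes. The high end came each time without replicate 1, where the remaining pair runs the same way. The same runs gave X differences of -0.3319 to 0.04874, chromosome 4 differences of -0.1319 to 0.06866, proximal differences of -0.01832 to 0.2198 and a rho with GC of -0.1033 to 0.1364. Without replicate 3 the X lost its call (adjusted permutation p = 0.0528) and chromosome 4 gained one (0.0214), both from 2 arrays of opposite sign. With the signs aligned, 123 of 131 comparison values kept their direction and side of the threshold, or a count within 1.5 times. The alternatives run included the authors' deposited table and the fit with a dye term. Some of the 131 values could hardly fail. They include the correlations between arrays, whose direction the choice of signs had set. Without centring, the chromosome differences and the rho with GC cannot change. The X difference lost its call without replicate 2, at an adjusted permutation p of 0.0546, while leaving out each array in turn gave differences of 0.3319 to 0.3806. The other 7 are counts that follow from the size of the windows. Windows of 5 kb gave 19416 calls, 9414 higher and 10002 lower. Windows of 50 kb gave 2105 calls, 1014 higher and 1091 lower, in 287 domains. Over all these alternatives the adjusted permutation p of the X difference ran from 0.0297 to 0.0546. Of 160 values of the 16 named domains under these alternatives, 146 moved by less than 1 SD of the arrays and 14 by more. None changed sign. Leaving out an array, the dye term and the array weights only average the same arrays anew. Such a change cannot move a mean by 1 SD or turn its sign here, so those values are no support. Apart from the domain on U after normexp and loess, every move of more than 1 SD came from the authors' deposited table. Most named domains shrank by more than 1 SD there, such as X 3220001-3410000 from 1.22 to 1.01 and 3R 12470001-12790000 from -1.04 to -0.87. The ratios of that table were smaller as a whole. Their SD over probes was 0.561, 0.465 and 0.502 on replicates 1, 2 and 3, against 0.672, 0.523 and 0.579 for the scanner ratios. The named domains on 2L and 2R 260001-320000 stayed within 1 SD. The removal of centring moves both sides of a difference alike and says nothing about the chromosome comparisons. Signal was far above background for nearly all probes, and the largest shares of dim probes were on YHet and U. Each array held both populations, so its ratio already pairs them, and no further pairing was possible because the design holds 1 group. The alternatives listed for genes, gene lists and gene density were not run, since no probe could be placed in a gene.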

Other observations

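Tests of array orientation, of the aligned window calls, of arm ends and of domain lengths on the X were chosen only after the result was seen. A domains on the X were longer than A domains on the autosomes, with mean lengths of 167 kb over 79 domains and 101 kb over 322 domains (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted 3e-05 over 3 tests of length). B domains on the X were shorter, with 85.1 kb over 53 domains against 118 kb over 377 (permutation p = 0.0328, adjusted 0.0491). Domains were taken as independent in these tests, and a larger share of A windows on the X lengthens A runs by itself.

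The most extreme windows, named after their values were seen, were X 12560001-12570000 at 2.19 ± 0.27 and X 12630001-12640000 at 2.10 ± 0.25 on the A side. On the B side they were 2RHet 3130001-3140000 at -1.37 ± 0.31 with 7 probes and 2R 830001-840000 at -1.33 ± 0.16. The profile was largest on replicate 1, where the SD of probe ratios was 0.672, against 0.523 and 0.579 on replicates 2 and 3. The slope of replicate 2 on replicate 1 was 0.699 among the dimmest 20% of the arm probes and 0.773 among the brightest 20%. Noise in the probe values of replicate 1 lowers such a slope. The SD of replicate 2 over that of replicate 1 differed less, at 0.750 and 0.795 in the same classes.

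Replicate 1 ran opposite to replicates 2 and 3 under the labelled dyes. A dye bias that set the profile would give red over green the same sign on every array, and replicates 1 and 3 correlated at -0.9764. A ratio column turned in 1 of the files is argued against as well, since the ratio of the scanner's mean signals followed that column at 0.9736 or more on each array. It stays open whether channel 1 holds different populations on different arrays or the dyes of an array are labelled the wrong way round, which array is affected, and which side is the early population. With the signs aligned the lowest of the 3 pairs correlated at 0.965, but this follows from the correlations that prompted the question and is no separate evidence.

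The X lay on the A side of the autosomes. Among probes of like intensity the difference kept 1.023 times its size on the array where it kept least. A bias of dim probes therefore does not account for it. Among probes of like GC content it kept 0.9934 times. Mean probe GC was 41.3% on the X and 41.0% to 41.5% on the long autosomal arms, so matching on it could change little. The GC content of the genome was not examined, but that of the probes does not account for the X difference. A few stretches did not carry it, since the difference of the medians of 1 Mb blocks was 1.262 times the mean difference and 22 of 23 blocks on the X lay above the autosomal median block. No biological explanation was tested, because the design holds 1 cell line and no other karyotype.

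Window ratios were skewed towards the A side, with a skewness of 0.51 on replicates 1 and 2. If the red channel had the wider range, red over green would be skewed the same way on every array, and the aligned skewness of replicate 3 would lie below 0. It was 0.4017, which argues against that explanation. No biological explanation was tested.

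Under the labelled dyes limma called 0 windows, and each of the 4 possible sets of signs, the labelled set included, called at least that number. The highest other count, 10027, came from the aligned set, which was chosen from the correlations between the arrays and adds no evidence to them. A comparison with a count of 0 excludes nothing. The aligned set called 10027 windows, and 1 of the 4 sets, the aligned set itself, gave as many, with 0 as the highest other count. With 4 sets, the share cannot fall under 0.05.

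As a hypothesis of the same kind as the proximal comparison, the distal 1 Mb of the long arms was set against the rest of the arms. The difference was 0.09 ± 0.03 with a circular-shift permutation p of 0.5625. Distal means were 0.42 on 3L, 0.33 on the X and 0.09 on 2L, but -0.04 on 2R and -0.19 on 3R, so the arm ends did not share a side.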
